A study of Escherichia coli with 6 samples.

How the data were processed

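One table of 6 samples was used, with a value per probe for 3 control and 3 current-exposed samples of Escherichia coli. Per the labels' protocols, 33P-labelled cDNA was made from total RNA by the StripAble cDNA synthesis method. The deposited values are linear intensities, and the scanner, the background treatment, the software and any scaling by the authors are not given in the sources used here. All deposited intensities are whole multiples of 0.0005 (within 0.001 of a step), and 49.9% of them are odd multiples, as a mean of 2 readings of 3 decimals would be. No background or detection value came with the intensities, so no probe could be called absent, and the number of arrays limits the precision.

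Groups and replicate numbers were taken from the labels. Design, gene lists, the rule for named genes and the alternatives were set before the data were examined. Probes were named through the platform annotation that goes with the table: 4095 probes have 1 symbol, none has several and 195 have none and keep their probe number. Symbols were updated through their gene identifiers to the RefSeq annotation of assembly ASM584v2, in which 4094 were found. The files name no genome build, so no coordinates are given and that annotation served for names and for which genes are neighbours.

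Array medians differed by up to 1.82 on the log2 scale, above the limit of 0.05 set beforehand for leaving arrays unscaled, so intensities were quantile normalised between arrays. The 16 values deposited as 0 were set to the 5th percentile of the positive normalised values (27346.5) before log2. Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, exposed minus control, two-sided, without covariates, with Benjamini-Hochberg adjustment over 4290 probes and a threshold of 0.05. Probes were not averaged, since each had its own value and name. Errors of log2 changes are standard errors from that model, and adjusted p-values of single genes are limma's.

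The 31 gene lists hold 773 entries, of which 769 were measured. They were tested with camera of limma at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists, and again with a correlation estimated per list, with ranks and with fry, which compares no list with other genes. Members were also adjusted over the list alone. Each gene is named by the symbol of its probe, and close copies in the genome can share signal. Named genes are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold, above the 25th percentile of mean log2 level and with groups that do not overlap. In each list, the 2 members with the largest rise and the 2 with the largest fall past the threshold were added, or the member with the smallest p where none passed. Other genes named in the text, such as nirD, hycI, fnr, nuoK, nuoN, fepD, fepG, pstC, aroC, ilvH and guaB, were chosen after their values were seen.

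The distance between groups was tested over all 10 splits of the arrays into 3 and 3. The gene test was tried on simulated arrays of 4290 genes with the spread of these data. It recovered 61% of genes changed by a log2 of 1 and 95% of genes changed by 2, with 9 false calls among unchanged genes. With 2 controls against 3 exposed arrays it recovered 40% and 86%, with 4 false calls. Noise was drawn independently per probe, with the same SD in both groups. Layout effects shared by probes and an outlying array were not simulated, so these rates do not cover them. The alternatives were the values as deposited, median centring, cyclic loess, a floor or a pseudocount at the 25th percentile (60184.6), leaving out probes below the 25th or 50th percentile, eBayes with an intensity trend and with robust settings, array weights, the replicate number as a block, leaving out each array, and for distances the Spearman correlation. After the data were seen, 2 corrections for the layout of the array were added, each made per array on deviations from the probe's mean. One removed the median of each of 96 recurring probe positions, the other the mean of up to 6 plate neighbours, the nearest probes at spacings of 96 probe numbers. Plots were drawn with matplotlib 3.10.9.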

Results

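Escherichia coli that had reached stationary phase after 18 h of growth in LB without NaCl received direct current in electroporation cuvettes, or stayed at room temperature without current. The current was 5 mA at 2 V (2.5 mA per square cm) through 2 ml of cell suspension with 2 mm between the plates; the length of exposure is not given in the sources used here. Transcripts of 3 control and 3 current-exposed samples were measured as 33P-labelled cDNA on an array of 4290 probes. The labels call the samples of a group biological replicates. They also describe cuvettes run together in series, so the p-values measure the spread between these samples, which may in part be technical.

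Signal was weaker on all 3 exposed arrays. The median deposited intensity was 133263, 132592 and 143804 on control arrays 1 to 3 and 40799.9, 43325.8 and 77168.9 on exposed arrays 1 to 3. On the log2 scale the array medians averaged 17.06 ± 0.07 in controls and 15.65 ± 0.51 after current (SD, n = 3 each), which puts the controls 2.65-fold higher, with no overlap between the groups. Of all deposited values 16 were 0, of which 4 lay on exposed array 1 and 8 on exposed array 2. The range of signal differed too: the 95th percentile of intensity over the 5th was 8.46 to 9.55 on control arrays and 13.2 to 14.4 on exposed arrays. Quantile normalisation set the 6 arrays to a common distribution, so each change given here is relative to the other transcripts on the same arrays. Strength and range of signal went with exposure, so calls made by current cannot be told apart from calls made by this difference between arrays. In the values as deposited the median probe shifted by a log2 of -1.52, and changes against that shift are the comparable ones.

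**Figure D1:**
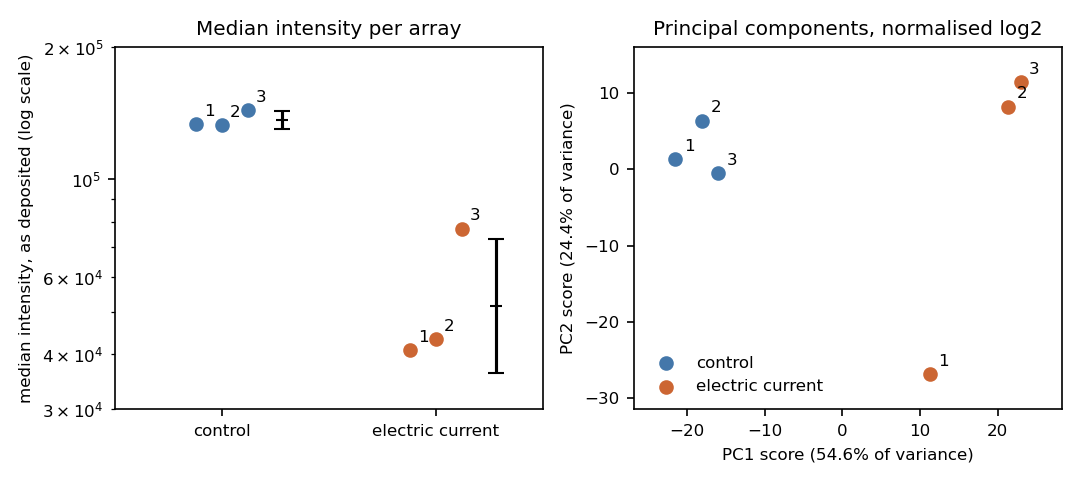
Left, median deposited intensity of each array (log axis) by group, numbered by replicate, with the mean and SD of each group on the log scale. Right, scores of the 6 normalised arrays on principal components 1 and 2 (54.6% and 24.4% of variance), where exposed array 1 sits away from exposed arrays 2 and 3.

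The arrays of the groups lay apart. Pearson correlations of normalised log2 values, across genes, were 0.919 to 0.938 within controls, 0.819 to 0.959 within the exposed group and 0.753 to 0.811 between the groups. The mean distance (1 minus the correlation) was larger between than within groups by 0.116, with an exact one-sided permutation p of 0.1, the smallest that 10 splits of 3 against 3 allow. Exposed array 1 had the lowest correlations within its group, and exposed arrays 2 and 3 the highest.

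The comparison of the groups asks which genes electric current induced or lowered. Transcripts of hycD and hycC, neighbouring genes for membrane subunits of the formate hydrogenlyase complex, were 6.68-fold and 5.28-fold higher after current. Genes of arginine and purine synthesis (argF and purE) and of the cytochrome bo oxidase (cyoC) rose 4.09-fold to 4.87-fold. The largest falls were those of the prophage tail fibre assembly genes tfaS, tfaE and tfaP and of the prophage gene yfdK, which were 3.45-fold to 3.90-fold lower. Of 4290 probes, 737 (17.2%) passed an adjusted p of 0.05 in limma, 349 higher and 388 lower. At least 2-fold differences were found for 193 of the higher and 45 of the lower probes, and 16 probes were at least 4-fold higher.

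The count depended on single arrays and on the scaling. It was 40, 86 and 341 without control replicate 1, 2 or 3, and 1638, 166 and 216 without exposed replicate 1, 2 or 3, and the share of higher calls was 47.4% against 61.4% with cyclic loess and 0.22% in the values as deposited.

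Among the 12 genes with the largest rises under the rule for named genes, hycD rose by a log2 of 2.74 ± 0.20 (SE, n = 3 per group, limma adjusted p = 0.000849). The largest rise of any probe, a log2 of 4.21, was on a probe outside that rule. The gene hycC rose by 2.40 ± 0.55 (adjusted p = 0.0255). The SD of hycC was 1.34 in the exposed group against 0.15 in controls. The fimbrial usher gene sfmD rose by 2.33 ± 0.36, argF by 2.28 ± 0.41, purE by 2.26 ± 0.21 (adjusted p = 0.00427) and cyoC by 2.03 ± 0.34. The glycolate operon gene glcG (2.05 ± 0.36), the predicted permease gene yraQ (2.03 ± 0.33), kduD of hexuronate breakdown (1.93 ± 0.36), the peptidyl-prolyl isomerase gene fkpB (1.92 ± 0.29) and yfgH (1.90 ± 0.36) also rose, as did the unnamed probe 3082 (2.50 ± 0.43). The probe of argF can also bind transcripts of its close copy argI, so its value is uncertain.

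The 12 largest falls under the same rule were led by tfaS (-1.96 ± 0.46), yfdK (-1.95 ± 0.34), tfaE (-1.85 ± 0.28) and tfaP (-1.78 ± 0.25). The 3 tfa genes are close copies, and the share of each in the signal is uncertain. The gene yjgH (-1.67 ± 0.19, adjusted p = 0.00547), the antitoxin gene relB (-1.48 ± 0.41) and dpaA, which encodes an enzyme that releases lipoprotein from the cell wall (-1.45 ± 0.18, adjusted p = 0.00619), fell too. So did the unnamed probe 4224 (-1.41 ± 0.29), yrdB (-1.36 ± 0.20), the lysine acetyltransferase gene yiaC (-1.32 ± 0.25), yhiS (-1.26 ± 0.28) and yifN (-1.26 ± 0.20). Of all probes, 1747 (40.7%) had 3 exposed values on one side of the 3 control values. By chance this share averages 10% over all splits of the arrays. All probes share the same 6 arrays, so the share in 1 split can lie far from 10% and is not a test. Of all 87 named genes, 10 were called in each of the 6 fits that left out an array: hycD, purE, fkpB, dinI, ilvA, gatB, tfaE, tfaP, yjgH and dpaA. Another 27, hycC among them, were called in 1 of these fits, and tfaS was called in 2.

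**Figure D2:**
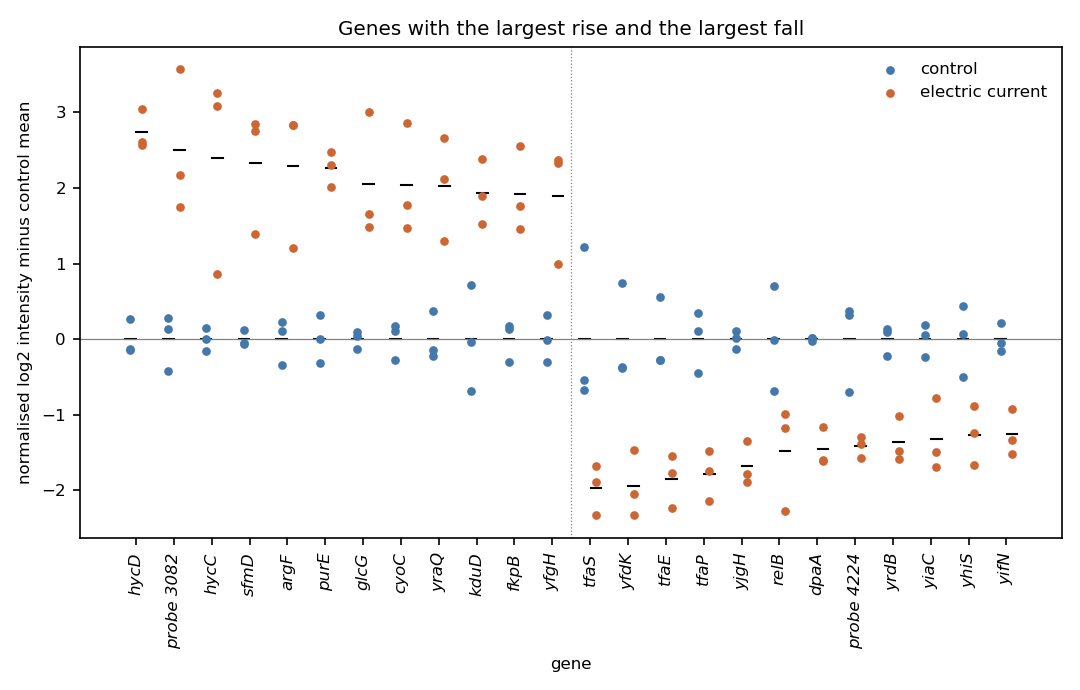
Normalised log2 intensity of the 12 genes with the largest rise and the 12 with the largest fall under the rule for named genes. Each array is shown minus the control mean of its gene, and black bars are group means. Exposed values of hycD lie closely together, those of hycC are spread (SD 1.34).

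Genes were also grouped in 31 lists of regulons and pathways. In 6 of them the members stood above other genes in camera with a preset correlation, and in no list did they stand below. A split with controls 1 and 2 and exposed array 1 on one side also called 6 lists. The number of list calls thus does not set the real grouping apart. With a correlation estimated for each list, no list passed, and the smallest adjusted p was 0.522. That form of camera also uses the few residual degrees of freedom of the 6 arrays. Sulfur assimilation lost its call at an estimated correlation of 0.00108, below the preset 0.01. The lost calls thus do not show that correlation between genes made them. The calls of phosphate starvation, anaerobic respiration and iron acquisition held in each of the 6 fits that left out an array, with fewer genes called in 5 of those fits. Those of aerobic electron transport, amino acid biosynthesis and sulfur assimilation did not. Ranges of list medians below are over 19 alternative settings, with medians of the values as deposited taken against their shift.

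In anaerobic respiration and hydrogenases, 12 of 61 genes rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 change of 0.18 (camera adjusted p = 0.00218; adjusted p = 0.522 with an estimated correlation). Besides hycD and hycC, the nitrite reductase subunit gene nirD rose by 1.60, the gene for the hydrogenase maturation protease hycI by 1.16 and fnr, the regulator of anaerobic respiration, by 1.12. The one fall was of napC, a periplasmic nitrate reductase cytochrome (-0.56 ± 0.16). The median ran from 0.12 (pseudocount at the 25th percentile) to 0.33 (values as deposited). Higher genes numbered 1, 2 and 8 without control replicate 1, 2 or 3, and 18, 3 and 4 without exposed replicate 1, 2 or 3.

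Aerobic electron transport had 4 higher genes of 23 and none lower, the same counts as adjusted over the list alone. Its median was 0.24 (camera adjusted p = 0.0251; adjusted p = 0.673 with an estimated correlation). They were cyoC and the NADH dehydrogenase subunit genes nuoF (1.18 ± 0.28), nuoK (0.98) and nuoN (0.88). The higher genes numbered 0, 0 and 5 without control replicate 1, 2 or 3, and 9, 1 and 2 without exposed replicate 1, 2 or 3. The list's call was lost without control replicate 1 (adjusted p = 0.0861), without exposed replicate 3 (adjusted p = 0.119) and with plate neighbours removed (adjusted p = 0.0585). Its median ran from 0.13 (without exposed replicate 3) to 0.44 (values as deposited).

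Iron acquisition genes, repressed by Fur when iron is ample, had 10 of 33 members higher and none lower (11 and 1 adjusted over the list alone). The median was 0.32 (camera adjusted p = 0.00253; adjusted p = 0.522 with an estimated correlation), and from 0.20 (plate neighbours removed) to 0.47 (values as deposited) over the settings. The ferric citrate transport gene fecC rose by 1.85 ± 0.48 and the ferrichrome permease gene fhuB by 1.81 ± 0.48; fepD and fepG of enterobactin uptake rose by 1.51 and 1.43. The number of higher genes was 0, 1 and 5 without control replicate 1, 2 or 3, and 17, 6 and 5 without exposed replicate 1, 2 or 3.

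Phosphate starvation genes (PhoB) had a median of 0.56, with 7 of 28 genes higher and none lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.00218; adjusted p = 0.584 with an estimated correlation). Of the 7, 6 belong to the phn genes for uptake and use of phosphonates, including phnG (2.09 ± 0.33) and phnF (1.41 ± 0.34); the other was the phosphate transport gene pstC (0.92). The probe of phnG was dim, below the 25th percentile of brightness. Leaving out control replicate 1, 2 or 3 gave 0, 0 and 2 higher genes, and leaving out exposed replicate 1, 2 or 3 gave 17, 2 and 2. Over the settings the median ran from 0.33 (without exposed replicate 3) to 0.71 (array weights).

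Amino acid biosynthesis had 11 of 80 genes higher and 3 lower (12 and 3 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0260; adjusted p = 0.522 with an estimated correlation). Beside argF, the threonine deaminase gene ilvA rose by 1.65 ± 0.24 and the chorismate synthase gene aroC by 1.42. The methionine pathway gene metF fell by 1.03 on the log2 scale, and aroL (-0.72) and ilvH (-0.62) fell as well. Leaving out control replicate 1, 2 or 3 gave 1, 5 and 9 higher genes and 0, 0 and 2 lower, and leaving out exposed replicate 1, 2 or 3 gave 26, 8 and 8 higher and 7, 1 and 1 lower. The list's call was lost without control replicate 3 (adjusted p = 0.0562), exposed replicate 2 (adjusted p = 0.0556) or exposed replicate 3 (adjusted p = 0.0782), with probes below the 25th or 50th percentile left out (adjusted p = 0.0708 and 0.0763) and with plate neighbours removed (adjusted p = 0.0501). The median of this list ran from 0.07 (floor at the 25th percentile) to 0.27 (without exposed replicate 1).

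Sulfur assimilation had 5 of 28 genes higher and none lower, the same counts as adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.0271; adjusted p = 0.522 with an estimated correlation). The serine acetyltransferase gene cysE (1.61 ± 0.24) and the alkanesulfonate monooxygenase gene ssuD (1.03 ± 0.29) rose most. Without control replicate 1, 2 or 3 the higher genes were 0, 0 and 2, and without exposed replicate 1, 2 or 3 they were 10, 1 and 1. The list's call was lost without control replicate 2 (adjusted p = 0.0566) and without exposed replicate 3 (adjusted p = 0.0782), and with either correction for the layout of the array (adjusted p = 0.121 and 0.266). Settings moved the median from 0.19 (pseudocount at the 25th percentile) to 0.48 (values as deposited).

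**Figure D3:**
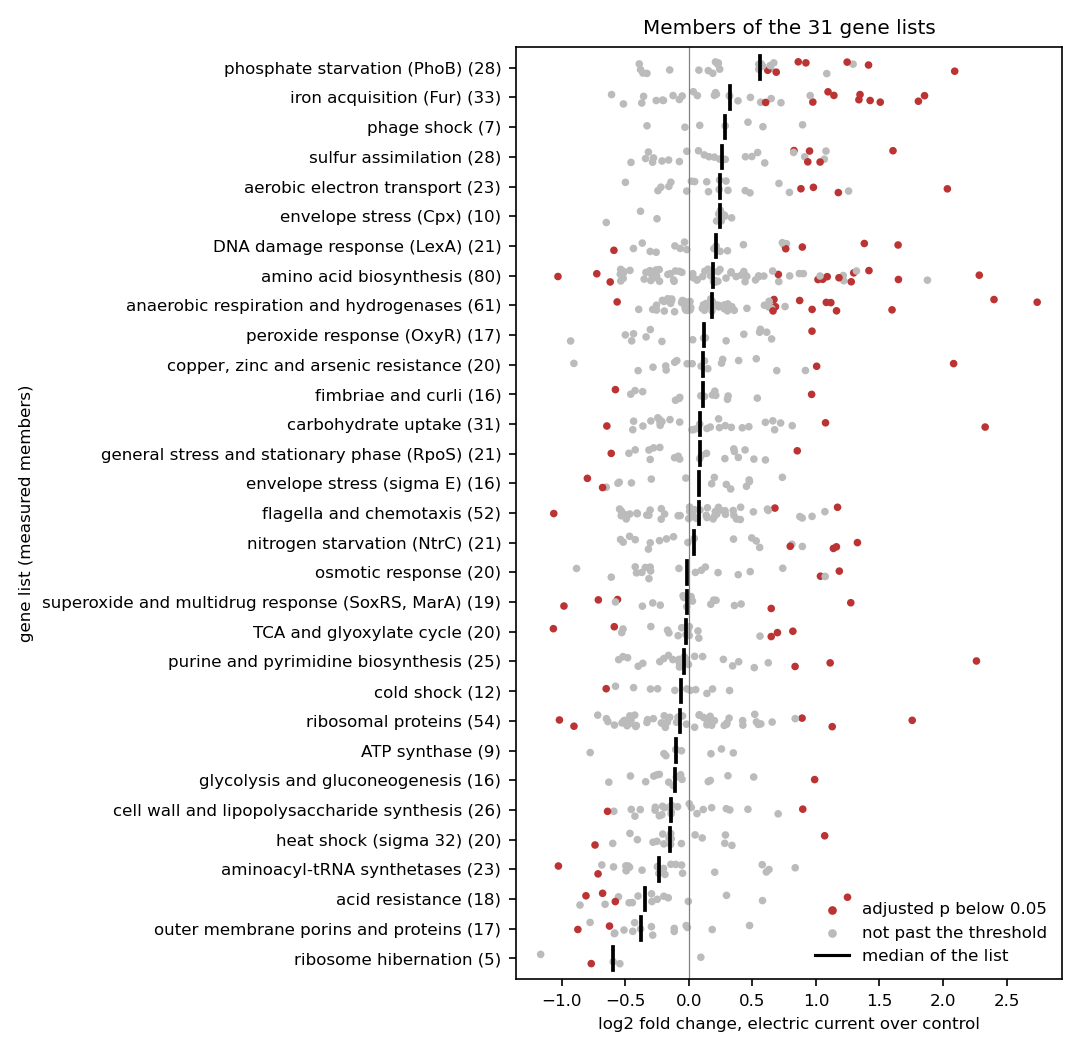
Log2 fold change, exposed over control, of each measured member of the 31 lists, with the number of members in brackets; red points passed an adjusted p of 0.05, grey points did not, and bars are list medians. Phosphate starvation has a median of 0.56 (0.33 without exposed replicate 3) and ribosome hibernation one of -0.59 (-0.19 with well position removed).

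In at least 1 setting the median of each of the 31 lists, the 6 called ones among them, moved by 1.5 times or more or changed sign. The other 25 lists did not pass camera. Outer membrane porins and proteins came nearest, with a median of -0.38 and adjusted p = 0.0707, and nmpC (-0.87 ± 0.19) and the vitamin receptor gene btuB (-0.62 ± 0.16) lower, 2 of 17 genes. This lower list passed camera with a floor at the 25th percentile (adjusted p = 0.0112), with probes below that percentile left out (0.0272) and with plate neighbours removed (0.0237). In fry, which tests whether the genes of a list move one way and not whether they differ from other genes, its adjusted p was 0.000367. In acid resistance (median -0.35, adjusted p = 0.119), 3 of 18 genes fell, 6 adjusted over the list alone, among them the periplasmic chaperone gene hdeA (-0.81 ± 0.16) and gadA (-0.68 ± 0.20), a close copy of gadB, while the acid shock gene asr rose by 1.25 ± 0.27. Ribosome hibernation had a median of -0.59 (-0.19 with well position removed; adjusted p = 0.140), with hpf lower (-0.77 ± 0.15), 1 of 5 genes and 2 adjusted over the list alone.

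Stress regulons gave single genes in both directions. Of the LexA list of DNA damage genes, 4 of 21 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.22, and 0.07 to 0.42 over the settings; adjusted p = 0.135; 1 higher gene without control replicate 1, 2 or 3), with dinI at 1.65 ± 0.23, dinF at 1.38 ± 0.32 and ydjM at -0.59 ± 0.16. The superoxide regulator gene soxS rose by 1.27 ± 0.26 and fumC by 0.65 ± 0.18, while ribA (-0.98 ± 0.16) and the efflux pump gene acrA (-0.71 ± 0.16) fell, so that 2 of 19 SoxRS and MarA genes rose and 3 fell (2 and 4 adjusted over the list alone; median -0.02, adjusted p = 0.947). The peroxide regulator gene oxyR rose by 0.97 ± 0.17, the only call among 17 OxyR genes (median 0.12, adjusted p = 0.552). In the heat shock list the chaperonin gene groS rose (1.07 ± 0.18) and the protease gene clpP fell (-0.74 ± 0.18), 2 of 20 (median -0.14, adjusted p = 0.708). In the RpoS list osmE rose (0.85 ± 0.20) and uspB fell (-0.61 ± 0.16), 2 of 21 (median 0.09, adjusted p = 0.708). The probes of dinI, groS, osmE and hpf were dim, below the 25th percentile of brightness.

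For the envelope, the outer membrane assembly genes bamD (-0.80 ± 0.17) and bamA (-0.68 ± 0.16) fell, 2 of 16 sigma E genes, with 1 higher and 5 lower adjusted over the list alone; the median was 0.08, the mean -0.05, and adjusted p = 0.947. No phage shock gene of 7 passed (median 0.29, adjusted p = 0.264), nearest pspD at 0.90 ± 0.28 with limma adjusted p = 0.0578. No Cpx gene of 10 passed either (median 0.24, adjusted p = 0.667), nearest degP at -0.65 ± 0.20 with limma adjusted p = 0.0544. Cell wall and lipopolysaccharide synthesis had kdsB higher (0.90 ± 0.15, a dim probe) and lpxH lower (-0.64 ± 0.18) of 26 genes (1 higher and 0 lower adjusted over the list alone; median -0.14, adjusted p = 0.947). The curli regulator gene csgD (0.97 ± 0.22, dim) rose and the type 1 fimbria gene fimA (-0.58 ± 0.16) fell, 2 of 16 (median 0.11, adjusted p = 0.708).

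In translation, the ribosomal protein genes rpmC (1.76 ± 0.32) and rpsN (1.13 ± 0.25) rose and rplL (-1.02 ± 0.23) and rpmF (-0.90 ± 0.20) fell, among 3 higher and 2 lower of 54 genes (2 and 2 adjusted over the list alone; median -0.07, mean -0.01, test direction up, adjusted p = 0.947). Among 23 aminoacyl-tRNA synthetases lysU (-1.02 ± 0.17), a close copy of lysS, and aspS (-0.71 ± 0.19) fell (median -0.24, adjusted p = 0.264). Of 12 cold shock genes cspB fell (-0.65 ± 0.18, dim), with 0 calls adjusted over the list alone (median -0.06, adjusted p = 0.748). In motility fliE (1.17 ± 0.23) and the master regulator gene flhC (0.68 ± 0.18, dim) rose and the flagellin chaperone gene fliS fell (-1.06 ± 0.16), 3 of 52 genes (1 higher and 1 lower adjusted over the list alone; median 0.08, adjusted p = 0.418).

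In central metabolism, 3 of 20 TCA and glyoxylate cycle genes rose and 2 fell, among them sucB (0.82 ± 0.24), gltA (0.70 ± 0.20), aceK (-1.06 ± 0.18) and sdhB (-0.59 ± 0.16); the median was -0.02 while the test pointed up (adjusted p = 0.947). The glycolytic gene pgk rose by 0.99 ± 0.15, the only call among 16 (median -0.11, adjusted p = 0.947). No ATP synthase gene of 9 passed (median -0.10, test direction up, adjusted p = 0.947), nearest atpG at -0.77 ± 0.31 with limma adjusted p = 0.106. In nucleotide synthesis purE, pyrF (1.11 ± 0.17, dim) and guaB (0.84) rose, 3 of 25, with a median of -0.04 and a mean of 0.13 (adjusted p = 0.590).

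Transport lists held some of the largest rises. The galactitol uptake gene gatB rose by 2.33 ± 0.25 from a dim control level (limma adjusted p = 0.00547), rbsC rose by 1.08 ± 0.30 and rbsA of the same ribose operon fell (-0.64 ± 0.18), 3 of 31 carbohydrate uptake genes (1 higher and 0 lower adjusted over the list alone; median 0.09, adjusted p = 0.264). The copper exporter gene copA rose by 2.08 ± 0.61, though its groups overlapped, and its regulator gene cueR by 1.01 ± 0.25, 2 of 20 metal resistance genes, with 0 adjusted over the list alone (median 0.11, adjusted p = 0.287). The gene kdpC of the Kdp potassium transporter (1.04 ± 0.24) and kdpE, which encodes the regulator of its operon (1.18 ± 0.33), rose, 2 of 20 osmotic genes and 1 adjusted over the list alone (median -0.01, mean 0.07, adjusted p = 0.796). In the NtrC list of nitrogen starvation 4 of 21 genes rose and none fell, led by glnG (1.33 ± 0.24) and astE (1.16 ± 0.20) (median 0.04, adjusted p = 0.264). In the lists given here without such counts, those adjusted over the list alone equalled the counts over all genes.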

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

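The removal of layout effects and the check on replicate numbers below were chosen after the data were seen; all else was planned. Counts of genes moved most. The values as deposited gave 3639 genes (8 higher, 3631 lower), because every exposed array was dimmer, and cyclic loess gave 219 lower genes. A floor at the 25th percentile gave 310 (105 higher, 205 lower), leaving out probes below the 50th percentile 443 (186 and 257), and array weights, which gave exposed array 1 a weight of 0.182, 2284 (997 and 1287). An adjusted p of 0.1 gave 1330 genes, and 238 were also changed at least 2-fold. Median centring gave 900 genes and cyclic loess 567, of which 598 and 546 were among the 737 calls, in the same direction. Removing the median of each of 96 probe positions gave 630 genes (399 higher, 231 lower), 527 of them among the 737; removing plate neighbours gave 1001 genes, 490 of them among the 737, and ended the calls of aerobic electron transport (adjusted p = 0.0585), amino acid biosynthesis (0.0501) and sulfur assimilation (0.266).

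Leaving out 1 array gave 40 (without control replicate 1) to 1638 genes (without exposed replicate 1), 33 to 763 of them higher and 7 to 875 lower, and 3 (without exposed replicate 3) to 6 lists. Without exposed array 1 all 737 calls were kept; 35 genes were called in each of the 6 fits. Simulated loss of 1 control cut recovery less (61% to 40%, 95% to 86%) than the fall to 40 genes. That argues against sample number as its only cause. Other causes were not tested.

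With an estimated correlation 0 lists passed. For sulfur assimilation the estimate was 0.00108, below the preset 0.01, so a larger correlation does not account for the loss of its call. For the other called lists the estimates were 0.0340 to 0.329. The estimated form also uses fewer degrees of freedom than the preset one, and the share of each in the lost calls was not tested. In fry, which tests lists against no change and not against other genes, 3 passed: anaerobic respiration, sulfur assimilation and the lower list of outer membrane porins. Over 22 alternatives, fry among them, adjusted p ran from 3.03e-06 to 0.584 for phosphate starvation (past the threshold in 20), from 0.000244 to 0.522 for iron acquisition (20), from 0.000293 to 0.522 for anaerobic respiration (21), from 0.00220 to 0.673 for aerobic electron transport (17), and from 0.00431 to 0.522 for both sulfur assimilation (17) and amino acid biosynthesis (14). Of lists not called, outer membrane porins ran from 0.000367 to 0.522 (past in 4), acid resistance from 0.0290 to 0.544 (2) and aminoacyl-tRNA synthetases from 0.0290 to 0.673 (1), all lower.

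With the replicate number as a block, 737 genes were called (377 higher, 360 lower), 625 of them shared with the fit without it, and 6 lists. Same-numbered arrays deviated together with r of 0.104, 0.312 and 0.0829 across genes, against -0.249 to 0.0869 for arrays of different numbers. Each exposed array correlated best with the control of its number, while control 3 correlated best with exposed array 1 (0.0869). Whether the numbers pair the samples stays open, and the planned fit without the block was kept.

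The distance between groups kept its direction under each alternative run for it. Direction was kept for the 87 named genes under the 3 other scalings, the values as deposited being read against their median shift. Over genes and alternatives, 1154 values kept their side of the threshold, 437 lost it and 16 gained it, and none reversed; of the list medians and tests 586 stayed, 60 medians of lists not called changed sign, 23 lost and 7 gained the threshold. No background values were given, so what dim probes can show is limited by a floor that could not be measured.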

Other observations

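The tests of gene families, insertion sequences, probe layout and exposed array 1 in this part were chosen after the results were seen.

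Genes whose symbols start with y, many of them of unassigned function when named, fell more often than other named genes: 160 of 1185 (13.5%) were lower and 73 higher, against 207 of 2910 (7.11%) lower and 259 higher (Fisher's exact test, p = 3.71e-10). Probes past number 2600 were lower more often (13.6%) than those before (6.08%), and among them the y genes were lower in 16.0% and other named genes in 11.3% (Fisher's exact test, p = 0.00771). Genes are not independent replicates in these tests. The counts are those of the fit with all 6 arrays. Over all probes, lower calls numbered 7, 26 and 148 without control replicate 1, 2 or 3, and 875, 40 and 50 without exposed replicate 1, 2 or 3. By the first 3 letters of the symbol, 249 families of 4 or more genes were tested for an excess of calls. The phn family had 6 of 13 genes higher, with an adjusted p of 0.0711, and the site-specific recombinase genes pin of prophages had 3 of 4 lower, with an adjusted p of 0.332; neither passed.

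Falls were commoner among bright probes. Of the 10% of probes with the highest mean level, 71 of 429 were lower and 34 higher. Of the 10% with the lowest mean level, 26 were lower and 40 higher. These counts also hold only for the fit with all arrays, as the lower calls over all probes fell to 7 without control replicate 1. When a single control array ranked the probes and the other arrays gave the change, the brightest 10% had a median of -0.38 to -0.44. When an exposed array ranked them, it had -0.03 (array 1), 0.33 (array 2) and 0.37 (array 3).

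Of the 10 splits of the 6 arrays into 3 and 3, the real one called 737 genes and the highest of the others 0, so 1 split reached that count. For lists the real split called 6 and the highest of the others 6 (controls 1 and 2 with exposed array 1), so 2 splits reached it. The remaining splits called 0 to 5 lists. List calls thus arose without a clean contrast of the groups, and their number does not set the real split apart. With 10 splits no share under 0.05 is possible. Each other split held control and exposed arrays on both sides, so any difference between the groups, of whatever cause, widened its residual spread. The 0 genes called there thus say nothing about the cause of the 737 calls.

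Calls were also set against the layout of the array. Deviations of arrays from their group mean correlated at a spacing of 96 probe numbers, the wells of a standard plate. Spearman values were 0.318, 0.496 and 0.436 for controls 1 to 3 and lower, at 0.129, 0.197 and 0.175, for exposed arrays 1 to 3. The value for the log2 changes was 0.142. The log2 changes also correlated at spacings of 1 (0.185) and 8 (0.127), against -0.00257 to 0.0979 at 94 further spacings. Removing the median of each of the 96 positions from each array left 527 of the 737 calls in the same direction, which argues against position on the plate as the cause of most of them. Removing the level of plate neighbours instead kept 490 of them among 1001 calls, so layout may contribute to the rest: neighbouring probes whose genes lie over 20 genes apart on the genome correlated at 0.148 (1035 pairs), and genome neighbours over 5 probe numbers apart at 0.0613 (2579 pairs). The pairs hycC and hycD, tfaE and tfaP, and tfaS and yfdK are neighbours on both.

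Insertion sequence genes, which encode transposases and related proteins of mobile elements, were lower as a family: 16 of 56 fell, none rose, and 49 had a negative change, with a median of -0.53 (adjusted p = 0.00457 among the families). Leaving out 1 array gave medians of -0.61 to -0.43 and 0 to 20 lower calls. Place on the array is argued against, as the 17 genes outside probes 300 to 400 had a median of -0.50 (95% bootstrap interval -0.63 to -0.32), below the -0.20 of 62 other probes inside. Means of families of 3 or more copies ran from -0.97 for insI to -0.06 for insA. Copies within a family resembled each other (permutation test of family labels, p = 9e-05), so the 56 genes are not independent. The adjusted p and the bootstrap interval treat them as independent. Both overstate the certainty, and the case against place on the array is weaker than the interval makes it look. Signal from genomic DNA was not tested. For brightness, the median lay at percentile 11.2 of 10000 random lists matched on control level. Control level enters the change itself, so those lists were drawn low (median -0.47) and cannot decide. The median lay below all lists matched on mean level (their median -0.14, lowest -0.45). The matchings thus differ, and each treats copies as independent probes. Brightness as the cause stays open. A lower transposase transcript level after current remains possible.

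Exposed array 1 stood apart from exposed arrays 2 and 3. Its deviations correlated at a spacing of 96 at 0.129, the lowest of the 6 arrays, which argues against layout as the main part of them. A correlation does not measure size, so a larger layout effect beside other deviations is not excluded. The changes of exposed array 1 against control 1 had a slope of 0.58 on those of exposed array 2 (against controls 2 and 3). On those of exposed array 3 the slope was 0.52. Exposed arrays 2 and 3 had slopes of 0.87 and 0.91 on each other. In reverse, exposed arrays 2 and 3 had slopes of 0.517 and 0.479 on exposed array 1. The SD of the changes against control 1 was 0.695, 0.707 and 0.742 for exposed arrays 1 to 3. The slopes thus do not tell a weaker response from a weaker correlation between arrays. The score of exposed array 1 on principal component 1 was 11.3, between the controls (-21.5 to -16.0) and exposed arrays 2 and 3 (21.3 and 22.9). A weaker response would give this. On component 2 its score was -26.8, with the other 5 arrays at -0.529 to 11.5, which a weaker response alone would not give. A weaker response, noise on that array, a response of another kind and a larger layout effect beside these stay open.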
